A study of Homo sapiens with 6 samples.

How the data were processed

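PRO-seq, a nuclear run-on method that sequences RNA made by engaged polymerases, was applied to SH-SY5Y, a human neuroblastoma line. Per the labels' protocols, nuclei were isolated with a detergent buffer, engaged RNA polymerases extended their transcripts in a run-on reaction, and the biotin-labelled RNA was fragmented, ligated to adapters, reverse transcribed and amplified. The labels give 3 groups of 2 libraries each: untreated cells, and cells given MPP+ at 0.1 mM, either over 0.5 h or over 24 h. The labels do not say whether the 2 replicates of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical, and n below counts libraries.

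Per the submitters' processing notes, the authors used cutadapt 1.16.5, Bowtie2 2.4.2, SAMtools 1.13, deepTools 3.5.1.0.0, featureCounts 2.0.1, DESeq2 2.11.40.6 and the genome build hg38. Per the file headers, the reads were trimmed and then aligned with Bowtie2. The strand, feature type and multimapping settings and the annotation release are not given in the sources used here. The deposited files of the authors hold, for each library, raw counts per gene without normalization. The authors' deposited tables of differential genes hold, per the file headers, a log2 fold change with its standard error, a Wald statistic (a score), a p-value and an adjusted p-value, and other columns with gene start and end positions. The direction of the ratio in the authors' deposited tables is not stated, and it was read from the counts.

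The count tables list 67051 gene identifiers. Of these, 42061 were named from a gene name table and 16489 from GENCODE 29, and 8501 stayed without a symbol. Those without a symbol held 0.872% to 1% of the counts of a library. Assigned counts per library were between 5983066 and 11707612. The table does not separate molecules from PCR copies, so intervals and floors below cover counting error only. A gene with 0 counts could hold up to 3 counts of the library total, which is between 2.56e-05% and 5.01e-05% of the assigned counts.

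The choices below were made before the data were examined, except where stated. Counts were filtered with filterByExpr by group, which left 23133 genes, normalized by TMM and fitted with the quasi-likelihood model of edgeR 4.0.16 in R 4.3.3 on all 6 libraries, with 1 coefficient per group and 3 residual degrees of freedom. The common biological coefficient of variation was 0.113 and the prior degrees of freedom were 6.34. Each p came from the two-sided quasi-likelihood F test and was adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. The comparisons were 0.5 h against untreated, 24 h against untreated and 24 h against 0.5 h. Values per group are TMM-scaled CPM as mean and SD of 2 libraries.

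A collection of 30 gene lists was fixed beforehand, with 982 symbols of which 977 matched a gene of the tables. The 4 mtDNA lists together held the mtDNA-encoded genes, and 26 lists held nuclear genes. A list with at least 3 tested members was tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided, adjusted by Benjamini-Hochberg over the 29 such lists. Camera was also run with an estimated correlation, and fry of limma beside it. Counts of members were given over all genes tested and adjusted over the list alone. Genes named in the text followed a rule fixed beforehand. It took the mtDNA protein-coding and rRNA genes, the genes of largest change past the threshold outside mtDNA and its nuclear copies, of which there were 0, and from each list up to 4 members with the smallest p. Of the mtDNA genes 6 are given in full and the others as a group, and not every list member that the rule takes is reported here. Genes named outside this rule are said to have been chosen after their values were seen.

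The share of counts on mtDNA-encoded genes was given per library with its exact Clopper-Pearson 95% interval and compared by an exact permutation test of the group means. A trend along mtDNA was tested by Spearman correlation across genes with 100000 permutations. The overlap of calls was set against 50 simulated data sets in which unchanged groups shared the controls. Replicates were checked for being copies of one another: the difference between the 2 libraries of a group had a chi-square per degree of freedom of 5.65 for untreated, 9.04 for 0.5 h and 4.15 for 24 h, above counting error alone.

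The pipeline was tested on simulated counts of all 23133 genes, in which 67 genes were changed by 1.5-fold, 67 by 2-fold and 66 by 4-fold. At 0.5 h, edgeR called 17.9% of genes with a simulated 1.5-fold change, 58.2% at 2-fold and 89.4% at 4-fold, and at 24 h it called 25.4%, 64.2% and 95.5%. Unchanged genes made up 11 of 125 calls at 0.5 h and 15 of 140 at 24 h. A planted list was called in both comparisons, and 0 of 20 random lists were. The genes were simulated independently, so this does not give the rate of false list calls where genes are correlated.

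Alternatives were DESeq2 1.42.0, edgeR's RLE and upper-quartile size factors, library size only, scaling on nuclear genes only, no filter on low counts, a mean of at least 50 counts, the replicate number as a block, only the 4 libraries compared, the edgeR likelihood ratio test, an estimated inter-gene correlation, and leaving out each library in turn. In the last, the group left with 1 library was assumed to vary like the other groups. DESeq2 on only the 4 libraries compared was added after the data were seen, as was leaving out libraries for the mtDNA share. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.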

Results

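Transcription in SH-SY5Y neuroblastoma cells was compared between untreated cells and cells exposed to MPP+ for 0.5 h or 24 h. MPP+ is a neurotoxin that enters cells through monoamine transporters and inhibits complex I of the respiratory chain. The measurement was PRO-seq, which counts RNA made by polymerases engaged in isolated nuclei and in any mitochondria that come along with them. Each of the 3 groups had 2 libraries. The untreated libraries held 7044839 and 8381006 assigned counts, the 0.5 h libraries 11707612 and 8714604, and the 24 h libraries 8573601 and 5983066.

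The question of the first comparison, which the series title raises, was whether mitochondrial transcription differed after MPP+. After 0.5 h of MPP+, counts on the genes of mitochondrial DNA fell, to a median 4.81-fold lower over 33 tested genes. No nuclear gene other than copies of mtDNA genes passed the test in the edgeR fit by group. This absence depends on that fit, which has no term for the replicate number, and on its filter on low counts and its test. The 13 mtDNA mRNAs, which encode subunits of the respiratory chain and ATP synthase, had log2 fold changes from -2.45 to -2.04, with a median 4.56-fold lower, and all 13 passed. Both mtDNA rRNAs, MT-RNR1 and MT-RNR2 of the mitochondrial ribosome, fell as well. Of the 33 tested mtDNA genes, 33 lay below 0.

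MT-RNR2 (ENSG00000210082.2, hg38 mtDNA 1671 to 3229) went from 261 ± 38.6 CPM (SD, n = 2) in untreated cells to 61.6 ± 9.78 CPM at 0.5 h, a log2 fold change of -2.08 ± 0.15 (SE, edgeR, adjusted p = 0.00112). MT-RNR1 (ENSG00000211459.2, 648 to 1601) went from 82.2 ± 12.2 to 19.2 ± 3.68 CPM, a log2 fold change of -2.10 ± 0.16 (adjusted p = 0.0012). MT-CO1 (ENSG00000198804.2, 5904 to 7445), a subunit of cytochrome c oxidase, changed by -2.26 ± 0.19 (adjusted p = 0.00172). MT-ND4 (ENSG00000198886.2, 10760 to 12137), of complex I, went from 137 ± 21.3 to 28.8 ± 6.16 CPM, or -2.27 ± 0.16 (adjusted p = 0.00112). MT-CYB (ENSG00000198727.2, 14747 to 15887), of complex III, went from 97.7 ± 0.528 to 23.6 ± 4.78 CPM, or -2.05 ± 0.15 (adjusted p = 0.00112). MT-ND6 (ENSG00000198695.2, 14149 to 14673), the mRNA encoded on the other strand, went from 20.9 ± 1.98 to 4.27 ± 0.187 CPM, or -2.28 ± 0.23 (adjusted p = 0.0054). The call of MT-ND6 was lost without 0.5 h replicate 1 (log2 fold change -2.33, adjusted p = 0.0682). Of the 18 tested mtDNA tRNA genes, 0 passed over all genes and 17 passed adjusted over the list alone, with a median log2 fold change of -2.33. The 3 testable mtDNA lists passed camera with the preset correlation, and they held with an estimated one, with adjusted p = 0.0137 for heavy-strand mRNAs, 0.0137 for heavy-strand tRNAs and 0.03 for light-strand genes.

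The share of assigned counts on mtDNA-encoded genes was 0.144% (95% Clopper-Pearson interval 0.141% to 0.147%) and 0.149% (0.146% to 0.151%) in the untreated libraries. It was 0.0275% (0.0266% to 0.0285%) and 0.0372% (0.0359% to 0.0385%) after 0.5 h, and 0.0334% (0.0322% to 0.0347%) and 0.029% (0.0277% to 0.0304%) after 24 h. The mean share was 0.146% ± 0.00309 (SD, n = 2) in untreated cells, 0.0324% ± 0.00683 at 0.5 h, which was 4.52-fold lower, and 0.0312% ± 0.00313 at 24 h, which was 4.69-fold lower. Both differences exceeded the spread between replicates. The exact permutation test gave p = 0.333 (two-sided, n = 2 per group) for each, which is the smallest p that the 6 splits of 2 against 2 allow, so this test could not reach the threshold.

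**Figure D1:**
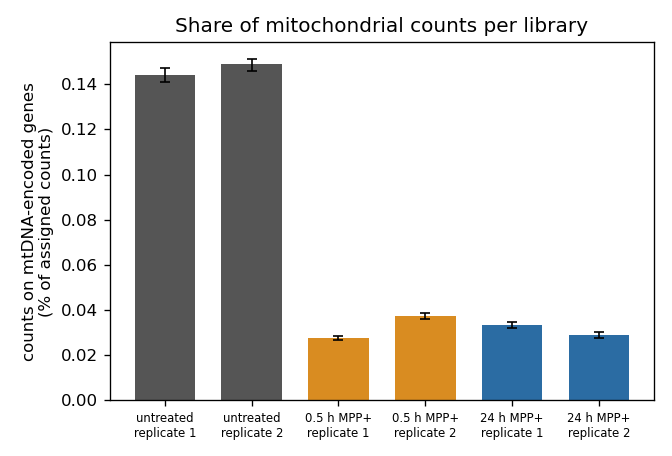
Bars give the share of counts on mtDNA-encoded genes, in percent of assigned counts, for each of the 6 libraries, and error bars the exact 95% interval for counting error. The untreated libraries lie at 0.144% and 0.149%, and the treated libraries between 0.0275% and 0.0372%.

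Among nuclear genes at 0.5 h, 2 passed the test, MTRNR2L8 (log2 fold change -1.98 ± 0.20, adjusted p = 0.00598) and MTRNR2L1 (-3.05 ± 0.36, adjusted p = 0.0145), both named outside the rule after their values were seen. Both are nuclear copies of the mitochondrial 16S rRNA gene that share its sequence. Of 20 tested nuclear copies of mtDNA genes, 19 lay below 0 with a median of -2.06. The fall was not shared by all copies. Some, picked after their values were seen, lay near 0, such as MTND5P19 (0.163), MTND3P8 (-0.0808) and MTCO1P1 (-0.18). In this fit edgeR called 0 genes higher and 17 lower, and DESeq2 also called 0 higher. At an unadjusted p under 0.05 there were 242 higher and 280 lower genes among the other 23080 nuclear genes. Chance alone gives about 1154 in both directions together where p-values are evenly spread. Fewer does not show that nuclear genes were unchanged, since the p-values of this fit may be cautious. With the replicate block, 1015 of all tested genes were higher and 760 lower at that unadjusted p. Without 0.5 h replicate 1, 9 genes were called lower, all 9 among the 17.

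Of 26 nuclear lists at 0.5 h, 3 passed camera, each with a higher median and 0 members past the threshold. Unadjusted p by fry was 0.35 for the noncoding RNA list, 0.696 for histones and 0.254 for mitochondrial ribosomal proteins. The RNA polymerase III and small stable noncoding RNA list had a median log2 fold change of 0.34 over 17 members (adjusted p = 0.000168, and adjusted p = 0.768 with an estimated correlation). Within it, the spliceosomal U4 genes RNU4-2 and RNU4-1 had 0.38 ± 0.10 and 0.60 ± 0.18 (adjusted p = 1 each). The replication-dependent histone list, genes transcribed mainly in S phase, had 0.17 over 49 members (adjusted p = 0.00235, and 0.99 with an estimated correlation), with H4C3 at 0.41 ± 0.19 and H2AC14 at 0.40 ± 0.20. Mitochondrial ribosomal protein genes had 0.080 over 57 members (adjusted p = 0.00235, and 0.768 with an estimated correlation), with MRPL4 at 0.62 ± 0.19 and MRPL44 at 0.56 ± 0.19.

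None of these 3 list results held without every single library. The noncoding RNA list lost its call without control replicate 2 (adjusted p = 0.37) or 0.5 h replicate 1 (median 0.19, adjusted p = 0.424). Histones lost it without control replicate 2 (median 0.069, adjusted p = 0.438) and turned to a lower median of -0.17 without 0.5 h replicate 1 (adjusted p = 0.0041), with 0.43 without 0.5 h replicate 2. Mitochondrial ribosomal proteins lost it without control replicate 1 (median 0.019, adjusted p = 0.574) or 0.5 h replicate 2 (median 0.031, adjusted p = 0.291), and stood at 0.15 and 0.14 without the other control or 0.5 h library. The number of lists called, mtDNA lists included, went from 6 to 11 without control replicate 1 and to 10 without 0.5 h replicate 2. Of the other 23 nuclear lists, the smallest adjusted p was 0.0694, for heat shock genes (median 0.093). The immediate early gene FOS had 0.58 ± 0.21 and DUSP2, a phosphatase of that list, had -1.41 ± 0.42, neither past the threshold (adjusted p = 1 each).

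The second comparison took the cells at 24 h. After 24 h of MPP+ the mtDNA genes were again lower, with a median 4.3-fold lower over 33 genes, and 33 of 33 lay below 0. Both rRNAs fell, MT-RNR1 by 7.72-fold and MT-RNR2 by 5.48-fold. Of the 13 mRNAs, 12 passed the test, all but MT-ATP8, and their log2 fold changes ran from -2.61 to -1.60. No nuclear gene other than copies of mtDNA genes passed in the same edgeR fit by group. This absence too depends on leaving the replicate number out of the fit, on the filter and on the test.

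MT-RNR1 had 10.6 ± 0.0767 CPM at 24 h (SD, n = 2) and a log2 fold change of -2.95 ± 0.18 (SE, adjusted p = 0.000401). MT-RNR2 had 47.4 ± 5.5 CPM and -2.45 ± 0.16 (adjusted p = 0.000401). MT-CYB had 15.9 ± 2.49 CPM and -2.61 ± 0.16 (adjusted p = 0.000401), and MT-ND4 had 28.8 ± 1.32 CPM and -2.26 ± 0.16 (adjusted p = 0.000633). MT-CO1 changed by -1.91 ± 0.19 (adjusted p = 0.00572) and MT-ND6 by -1.91 ± 0.23 (adjusted p = 0.0199). MT-CO1 lost its call without control replicate 1 (-1.82, adjusted p = 0.0525). MT-ND6 lost it without control replicate 1 (adjusted p = 0.0716), control replicate 2 (0.091), 24 h replicate 1 (0.0748) or 24 h replicate 2 (0.131), at log2 fold changes of -2.20 to -1.71. The 18 mtDNA tRNA genes had a median of -2.12, with 0 past the test over all genes and 18 adjusted over the list alone. The 3 mtDNA lists again held with an estimated correlation, with adjusted p = 0.029 for heavy-strand mRNAs, 0.029 for heavy-strand tRNAs and 0.0418 for light-strand genes.

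**Figure D2:**
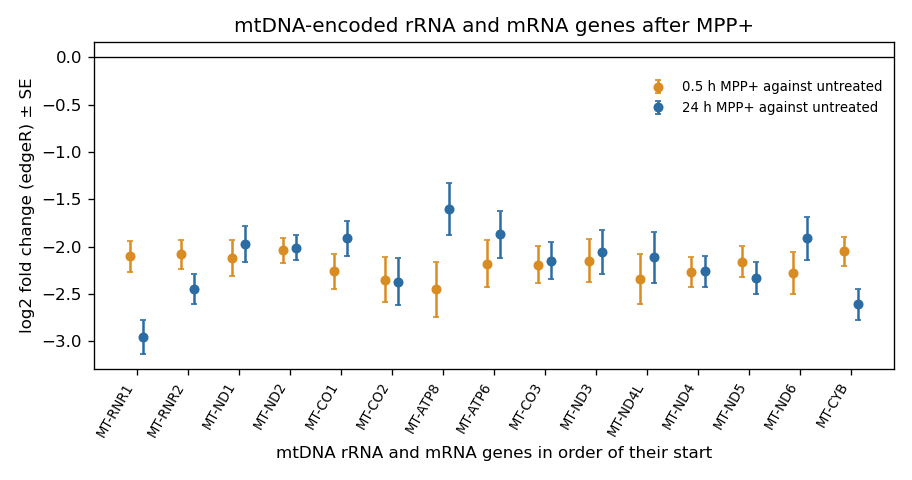
Points give the log2 fold change from edgeR against untreated cells, with its standard error, for 15 mtDNA rRNA and mRNA genes ordered by start on mtDNA (0.5 h and 24 h, 2 libraries per group). At 0.5 h the mRNAs lie between -2.45 and -2.04, and at 24 h MT-RNR1 lies lowest at -2.95.

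In all, edgeR called 16 genes lower and 0 higher at 24 h. Besides mtDNA genes these were 2 nuclear copies, named after their values were seen, MTRNR2L8 (-1.93 ± 0.21, adjusted p = 0.0105) and MTRNR2L12 (-2.61 ± 0.34, adjusted p = 0.0391). Of 20 tested copies 19 lay below 0, but some again lay near 0, such as MTND5P19 (-0.0199), also picked after its value was seen. At an unadjusted p under 0.05, 928 other nuclear genes were higher and 899 lower, where chance alone gives about 1154 in both directions together. DESeq2 called 13 genes higher at 24 h. The number called lower was 8 without control replicate 1, 10 without 24 h replicate 1 and 10 without 24 h replicate 2, each time among the 16. Without control replicate 2, or without 24 h replicate 2, edgeR called 1 gene higher.

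**Figure D3:**
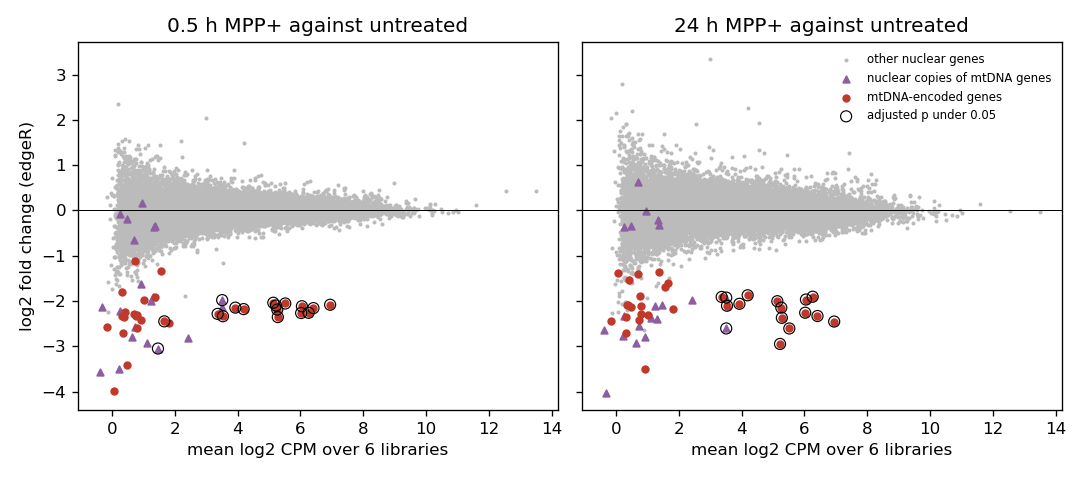
Each point is a gene: the horizontal axis gives its mean log2 CPM over 6 libraries and the vertical axis its log2 fold change from edgeR, at 0.5 h (left) and 24 h (right) against untreated. Circled genes passed an adjusted p of 0.05, 17 at 0.5 h and 16 at 24 h, and lie on mtDNA or are nuclear copies of its genes.

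Nuclear lists had small median differences at 24 h: 11 of 26 passed camera with the preset correlation, 6 lower and 5 higher. None of the 11 passed with an estimated correlation. Unadjusted p by fry was 0.00546 for mitochondrial transcription and mtDNA maintenance, 0.0118 for ribosome biogenesis and MYC targets and 0.0224 for p53 targets. For the others of the 11 it was 0.0825 to 0.438, with 0.22 for S phase and replication. Genes of S phase and DNA replication had a median log2 fold change of -0.18 over 40 members, 38 of them below 0 (adjusted p = 8.32e-09, and adjusted p = 0.641 with an estimated correlation). Of its members 0 passed over all genes and 2 passed adjusted over the list alone, among them the replicative helicase subunit MCM5 (-0.66 ± 0.15, adjusted p = 0.383). UNG, of base excision repair, had -0.52 ± 0.14, and UHRF1, which recruits the maintenance DNA methyltransferase, had -0.46 ± 0.13. The list kept its call without any 1 library, but its median was -0.035 without control replicate 1 (adjusted p = 0.0443), -0.34 without control replicate 2, -0.28 without 24 h replicate 1 and -0.10 without 24 h replicate 2.

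Lists of protein synthesis were lower as well. Ribosome biogenesis and MYC target genes had a median of -0.14 over 34 members, 30 below 0 (adjusted p = 0.000202, and adjusted p = 0.136 with an estimated correlation), and the call was kept without any 1 library. The nucleolar protein gene MYBBP1A (-0.54 ± 0.10, adjusted p = 0.252) passed adjusted over the list alone, and PES1, needed for 60S subunit maturation, had -0.36 ± 0.11 (adjusted p = 0.537). Cytosolic ribosomal protein genes had -0.15 over 71 members, 61 below 0 (adjusted p = 4.64e-06, and adjusted p = 0.641 with an estimated correlation). Among them RPL4 had -0.38 ± 0.10 and RPL10 -0.45 ± 0.12, and RPS28 went the other way at 0.69 ± 0.14 (adjusted p = 0.302). This list lost its call without control replicate 1 (median -0.036, adjusted p = 0.176) and had -0.26 without control replicate 2.

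Targets of ATF4, the transcription factor of the integrated stress response, had a median of -0.15 over 46 members (adjusted p = 0.0112, and adjusted p = 0.641 with an estimated correlation). The amino acid transporter gene SLC38A2 had -0.42 ± 0.11 and the tRNA synthetase genes WARS1 and AARS1 had -0.46 ± 0.13 and -0.35 ± 0.11, whereas STC2 had 0.52 ± 0.16, all without passing. The list lost its call without control replicate 1 (median -0.027, adjusted p = 0.861) or 24 h replicate 2 (adjusted p = 0.154). Mitochondrial chaperones and proteases had -0.15 over 16 members (adjusted p = 0.0112, and adjusted p = 0.641 with an estimated correlation), with the import pore TOMM40 at -0.38 ± 0.13 and the matrix protease LONP1 at -0.35 ± 0.13. They lost the call without control replicate 1 (median 0.0025 with the test still pointing lower, adjusted p = 0.275) or 24 h replicate 2 (median -0.065, adjusted p = 0.0828), and had -0.24 without control replicate 2. Nuclear genes of mitochondrial transcription and mtDNA maintenance had -0.082 over 32 members (adjusted p = 0.0403, and adjusted p = 0.364 with an estimated correlation). Among them were the coactivator PPRC1 at -0.54 ± 0.15 and TBRG4, which acts on mitochondrial RNA, at -0.29 ± 0.10. That call was lost without control replicate 1 (median -0.047, adjusted p = 0.106), control replicate 2 (0.0603), 24 h replicate 1 (0.0838) or 24 h replicate 2 (0.116). It was also lost under upper-quartile normalization (adjusted p = 0.0505) and where a mean of at least 50 counts was required (adjusted p = 0.0605).

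Among the 5 lists with higher values, p53 targets had a median of 0.20 over 23 members, 19 above 0 (adjusted p = 2.19e-05, and adjusted p = 0.305 with an estimated correlation), and kept the call without any 1 library. The antiproliferative gene BTG2 had 0.68 ± 0.17, ZMAT3 0.35 ± 0.10 and the cell cycle inhibitor CDKN1A 0.44 ± 0.15, with 0 members past the threshold. Replication-dependent histones had 0.29 over 49 members, 46 above 0 (adjusted p = 2.6e-08, and adjusted p = 0.641 with an estimated correlation), with H2AC14 at 0.69 ± 0.21 and H4C12 at 0.48 ± 0.15. Without 24 h replicate 1 the histone median was -0.034 and the call was lost (adjusted p = 0.799), and without 24 h replicate 2 it was 0.57. The RNA polymerase III and small noncoding RNA list had 0.45 over 17 members (adjusted p = 0.00184, and adjusted p = 0.641 with an estimated correlation). Its Y RNA genes RNY4 and RNY3 had 1.90 ± 0.36 (adjusted p = 0.252) and 2.26 ± 0.76 (adjusted p = 0.567), and RNY4 alone passed adjusted over the list alone. The list lost its call without control replicate 2 (median 0.14, adjusted p = 0.537) or 24 h replicate 1 (median 0.12, adjusted p = 0.526), and had 0.25 without control replicate 1. It also lost it where a mean of at least 50 counts was required (median -0.0043 with the test still pointing higher, adjusted p = 0.4).

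Heat shock genes had a median of 0.22 over 17 members (adjusted p = 0.0112, and adjusted p = 0.477 with an estimated correlation). HSPB1, a small heat shock protein gene, went from 31 ± 4.7 to 54.2 ± 1.98 CPM (0.80 ± 0.13, adjusted p = 0.146) and passed adjusted over the list alone, also without any 1 library. HSPA1A had 0.60 ± 0.25, and HSF1, the factor that drives the heat shock response, had -0.31 ± 0.12. The list lost its call without control replicate 2 (adjusted p = 0.058) or 24 h replicate 1 (median 0.067, adjusted p = 0.361). HIF targets of the hypoxia response had 0.13 over 31 members (adjusted p = 0.0112, and adjusted p = 0.641 with an estimated correlation). Of them BHLHE40 (2.80 ± 0.61), the collagen prolyl hydroxylase P4HA1 (0.47 ± 0.11) and adrenomedullin, ADM (0.76 ± 0.21), passed adjusted over the list alone, with adjusted p = 0.357, 0.439 and 0.519 over all genes. BHLHE40 had 0.203 ± 0.121 CPM in untreated cells and so few counts. That list lost its call without control replicate 2 (median -0.021 with the test still pointing higher, adjusted p = 0.997) or 24 h replicate 1 (median 0.020, adjusted p = 0.335), and had 0.25 without control replicate 1.

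**Figure D4:**
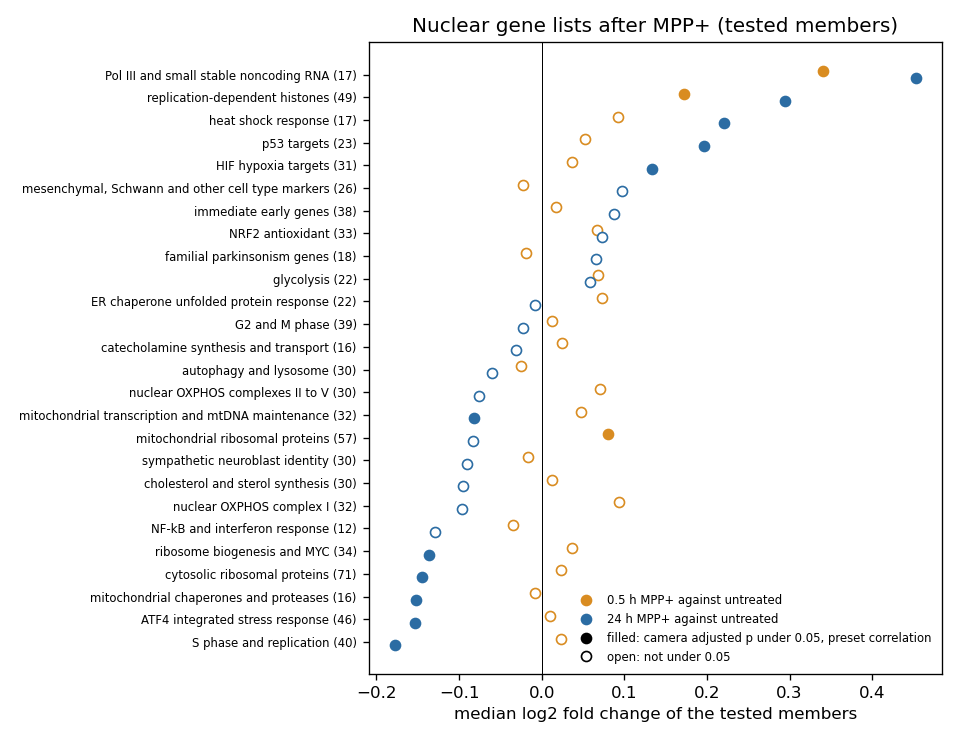
Points give the median log2 fold change of the tested members of each nuclear list, at 0.5 h and 24 h against untreated, with the number of tested members beside each name; filled points passed camera at the preset correlation and open points did not. At 24 h S phase genes lie lowest at -0.18 and the noncoding RNA list highest at 0.45, and 0 of the filled points pass with an estimated correlation.

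The other 15 nuclear lists did not pass at 24 h in the fit by group. Catecholamine synthesis and transport, the transmitter pathway of these cells, had a median of -0.031 (adjusted p = 0.886), with DBH at -0.20 ± 0.12 and QDPR at -0.20 ± 0.10. Sympathetic neuroblast identity had -0.091 (adjusted p = 0.2), with GAP43 at 0.24 ± 0.12, and markers of mesenchymal, Schwann and other cell types had 0.098 (adjusted p = 0.135), with NOTCH2 at 0.45 ± 0.13. Familial parkinsonism genes had 0.066 (adjusted p = 0.933), with PINK1 at -0.49 ± 0.23. Nuclear subunits of complex I had -0.096 (adjusted p = 0.163) and those of complexes II to V -0.075 (adjusted p = 0.244), with NDUFS7 at 0.76 ± 0.30 and COX7C at -0.40 ± 0.16. Mitochondrial ribosomal proteins had -0.083 (adjusted p = 0.0595), with MRPL35 at 0.47 ± 0.15. Antioxidant genes of NRF2 had 0.073 (adjusted p = 0.244), with NQO1 at 0.45 ± 0.15 and HMOX1 at 0.68 ± 0.25. Endoplasmic reticulum chaperones had -0.0076 (adjusted p = 0.886), with ERO1B at 0.54 ± 0.18. Immediate early genes had 0.087 (adjusted p = 0.163), with GADD45B at 0.95 ± 0.25, and NF-kB and interferon response genes had -0.13 (adjusted p = 0.771). In the latter OAS1 (0.86 ± 0.25) and NFKBIZ (0.42 ± 0.12) passed adjusted over the list alone.

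Glycolysis genes had 0.059 (adjusted p = 0.406), with PFKL at -0.29 ± 0.11, and sterol synthesis genes had -0.095 (adjusted p = 0.301), with SCD at -0.30 ± 0.095. The G2 and M phase list had -0.023 (adjusted p = 0.422), with BUB3 at -0.23 ± 0.10, and autophagy and lysosome genes had -0.061 (adjusted p = 0.406), with ULK1 at -0.34 ± 0.15. None of the nuclear genes named for 24 h passed the edgeR test over all genes. The median and the test pointed opposite ways for the parkinsonism and NF-kB lists, and the median and the mean for the parkinsonism, NF-kB and catecholamine lists. In total 10 nuclear list members passed adjusted over the list alone at 24 h, against 0 over all genes by edgeR. Of these 10, 1 remained without control replicate 1, 6 without control replicate 2, 1 without 24 h replicate 1 and 4 without 24 h replicate 2, HSPB1 each time. The number itself went from 10 to 2, 38, 1 and 41 in these fits, in the same order.

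The third comparison, 24 h against 0.5 h, asked whether the mtDNA genes differed between the exposure times. Over 33 mtDNA genes the median log2 fold change was 0.15, with 22 above 0 and 11 below, and the set did not pass (camera adjusted p = 0.772). MT-RNR1 had -0.85 ± 0.19 (adjusted p = 0.754 over all genes) and MT-RNR2 -0.37 ± 0.16 (adjusted p = 0.768). The median depended on single libraries: it was 0.40 without 0.5 h replicate 2 (adjusted p = 0.00245) and 0.27 without 24 h replicate 2 (adjusted p = 0.0164), but -0.16 without 0.5 h replicate 1 (adjusted p = 0.0769) and -0.042 without 24 h replicate 1 (adjusted p = 0.241). For single genes edgeR called 0 higher and 0 lower in the fit by group, and DESeq2, also by group, called 0 in each direction. At an unadjusted p under 0.05, 645 of 23080 other nuclear genes were higher and 835 lower. This absence of calls too depends on the filter, on the edgeR test used and on leaving the replicate number out. With it as a block, edgeR called 116 higher and 296 lower. Of 26 nuclear lists, 12 passed camera between the times, 9 lower and 3 higher at 24 h, and 0 with an estimated correlation, where the smallest adjusted p was 0.275.

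The 2 comparisons with untreated cells share the control libraries. They had 15 lower genes in common of 17 and 16, where simulated unchanged groups sharing the controls had a mean of 0.08 and at most 1 in 50 simulations. The simulation drew each gene independently, so it held no shift of the control libraries common to the mtDNA genes. It cannot tell whether such a shift gave the overlap. Along the heavy strand, from MT-RNR1 to MT-CYB, the rank correlation of position with log2 fold change across 14 genes was -0.24 at 0.5 h (permutation p = 0.398, adjusted p = 0.796; Pearson r = -0.17) and -0.068 at 24 h (permutation p = 0.819, adjusted p = 0.989; Pearson r = 0.056). For the 12 mRNAs alone it was -0.62 at 24 h (permutation p = 0.0378, adjusted p = 0.227 over 6 tests; Pearson r = -0.61). These are correlations across genes, which are not independent replicates.

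The authors' deposited table for 0.5 h lists 17 genes, of which 14 are mtDNA genes and 3 nuclear copies. The authors' deposited table for 24 h lists 24 genes, of which 14 are mtDNA genes, 2 nuclear copies and 8 other nuclear genes. In the authors' deposited tables all 17 and all 24 fold changes have the sign opposite to treated minus untreated counts, so they were read as untreated over treated. For MT-CO1 the authors' deposited table gives a log2 fold change of 1.43 ± 0.12 (SE) at 0.5 h and 1.33 ± 0.15 at 24 h in that direction. Of the 8 nuclear genes of the authors' deposited table, all had higher counts at 24 h here and 0 passed edgeR, with the smallest adjusted p = 0.0752 for CFAP418-AS1 (0.91 ± 0.13). The DESeq2 fit on all 6 libraries called all 8 of these genes of the authors' deposited table higher, with adjusted p from 9.33e-07 for AL592295.4 to 0.0176 for ANKMY2.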

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

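The rule that a list differs between the exposure times was set beforehand, and leaving out single libraries for these lists was chosen only after the results were seen. The direct comparison of 24 h with 0.5 h gave 12 nuclear lists an adjusted camera p under 0.05 at the preset correlation, and a difference between the 2 times is what singled them out. None passed with an estimated correlation, where the smallest adjusted p was 0.275. Unadjusted p by fry was 0.00122 for mitochondrial transcription and mtDNA maintenance, 0.0111 for ribosome biogenesis and MYC targets, and 0.0618 to 0.666 for the others of the 12. Lower at 24 h than at 0.5 h were S phase and replication (median log2 fold change -0.243), cytosolic ribosomal proteins (-0.176), mitochondrial ribosomal proteins (-0.176), ribosome biogenesis and MYC targets (-0.173), ATF4 targets (-0.159), nuclear complex I (-0.151), mitochondrial transcription and mtDNA maintenance (-0.147), mitochondrial chaperones and proteases (-0.129) and complexes II to V (-0.118). Higher were markers of mesenchymal, Schwann and other cell types (0.197), replication-dependent histones (0.175) and p53 targets (0.162).

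Of the 12, 8 kept the call without any 1 library. The ATF4 list lost it without 0.5 h replicate 1 (median -0.066, adjusted p = 0.996) or 24 h replicate 2 (adjusted p = 0.0526), and the chaperone list without 24 h replicate 2 (median -0.032, adjusted p = 0.0696). The cell type markers lost it without 0.5 h replicate 2 (adjusted p = 0.491), 24 h replicate 1 (median 0.13, adjusted p = 0.128) or 24 h replicate 2 (adjusted p = 0.0579). Histones turned lower, at -0.080 without 0.5 h replicate 2 (adjusted p = 0.0295) and -0.14 without 24 h replicate 1 (adjusted p = 0.00155), and were at 0.46 without 0.5 h replicate 1 and 0.42 without 24 h replicate 2. Medians also moved by over 1.5 times for complex I (-0.093) and complexes II to V (-0.028) and mitochondrial ribosomal proteins (-0.091) without 0.5 h replicate 2. Without 0.5 h replicate 1 they were -0.14 for S phase, -0.11 for cytosolic ribosomal proteins and -0.077 for chaperones, and without 24 h replicate 2 they were -0.16 for S phase, -0.093 for cytosolic ribosomal proteins and -0.11 for ribosome biogenesis. No explanation was tested for these differences.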

How the results depend on the processing

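Most alternatives were set before the files were opened, and DESeq2 on only the 4 libraries compared and leaving out libraries for the mtDNA share were chosen after seeing the data. The median fall of mtDNA genes kept its direction under each alternative, and its call under each for which camera was run, which leaves out DESeq2. For the likelihood ratio test, camera repeats the test of the main fit and adds nothing. The median lay between -2.44 and -1.95 at 0.5 h and between -2.21 and -1.92 at 24 h. The share stayed lower on leaving out libraries (3.94- to 5.31-fold and 4.38- to 5.04-fold lower). The counts of called genes moved most. At 0.5 h, with 0 higher and 17 lower, the counts were 20 and 46 without a filter on low counts, 15 and 42 with the replicate block and 1 and 41 by the likelihood ratio test, and leaving out 1 library gave 0 higher and 9 to 19 lower. At 24 h, with 0 and 16, they were 130 and 115 without a filter, 301 and 384 with the block and 40 and 63 by the likelihood ratio test. There 1 gene was higher with library size only, 13 by DESeq2 and 11 by DESeq2 on 4 libraries, and leaving out 1 library gave 0 to 1 higher and 8 to 16 lower. At 24 h against 0.5 h, with 0 and 0, they were 29 and 44 without a filter, 116 and 296 with the block, 5 and 8 by the likelihood ratio test, and 1 higher by DESeq2 on 4 libraries. All 17 and all 16 genes of the 2 comparisons were shared under no filter, block and likelihood ratio test. The block removes the difference between replicate numbers. These followed one another across groups, with correlations of 0.328, 0.293 and 0.312 of their deviations, from 2 pairs each. With 2 libraries per group, deviations from the group mean mirror one another, so the 2 pairs are only 1 independent comparison. The first principal component (34% of variance) separated the numbers. The labels give the numbers no meaning, so the block is not the reported result. The absence of nuclear calls rests in part on leaving it out. With the block, nuclear genes other than mtDNA copies were called 15 higher and 6 lower at 0.5 h. They were 301 and 342 at 24 h, and 116 and 295 at 24 h against 0.5 h. The absence also rests on the filter and the test, in fits without the block. Such nuclear calls at 24 h were 130 higher and 73 lower without a filter, 40 and 23 by the likelihood ratio test, and 13 higher by DESeq2. At 0.5 h they were 20 and 3 without a filter. On simulated data at 0.5 h and 24 h, unchanged genes made up 11 of 125 and 15 of 140 calls in the fit by group, 19 of 138 and 16 of 138 with the block, and 31 of 161 and 38 of 186 by the likelihood ratio test. The simulated libraries held no difference between replicate numbers. These rates therefore cannot show whether the nuclear calls with the block are false. Leaving out 1 library put the mtDNA median for 24 h against 0.5 h between -0.163 and 0.4. Lists called at 0.5 h were 6, with 10 without a filter, 3 with an estimated correlation and 6 to 11 on leaving out 1 library. Lists called at 24 h were 14, with 3 with an estimated correlation and 10 to 15 on leaving out 1 library. With the block, 7 lists were called at 0.5 h, with heat shock genes added (adjusted p = 0.0475), and 16 at 24 h, with sympathetic neuroblast identity (adjusted p = 0.00848) and mitochondrial ribosomal proteins (adjusted p = 0.049) added. The medians of the lists called against untreated cells had the same sign in DESeq2, 6 of 6 at 0.5 h and 14 of 14 at 24 h. The rank correlation along mtDNA for 24 h against 0.5 h (0.00659) turned to -0.497 in the 12 mRNAs. Of the named genes' values under alternatives, 0 reversed. Nuclear genes named for 24 h passed in 58 of 750 values, by block, no filter, likelihood ratio test and, for HSPB1 and RNY4, DESeq2, and those for 0.5 h in 2 of 237. Named mtDNA genes lost the call in 1 of 96 at 0.5 h and 5 of 96 at 24 h, each time on leaving out 1 library. In 5 cases an alternative gave no test value. The cause of these shifts was not tested.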

Other observations

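Chosen only after the result was seen were the tests at equal depth, without MT-RNR1, without the genes of the authors' deposited table, each leaving-out of single libraries, and the DESeq2 fit with a prior. Of the 13 genes that DESeq2 called higher at 24 h, 7 hold a nuclear tRNA gene or lie within 50 kb of one, and 6 of these 7 hold one within their bounds, whereas 2.03% of 22341 tested genes do either. These genes fall outside the naming rule and were chosen after their values were seen. They include the long noncoding RNA genes AL592295.4 (log2 fold change 1.28 ± 0.20 by edgeR, adjusted p = 0.116) and CFAP418-AS1 (0.91 ± 0.13, adjusted p = 0.0752), HES7, a Notch target (1.27 ± 0.23, adjusted p = 0.215), CTC1, of the telomere-binding CST complex (0.73 ± 0.12, adjusted p = 0.165), and LTA4H, of leukotriene synthesis (0.70 ± 0.14, adjusted p = 0.302). The 69 tested genes that hold a tRNA gene had a median of 0.26 at 24 h, 53 of them above 0. None passed over all genes by edgeR and 26 did adjusted over the list alone, 24 higher and 2 lower. In 10000 random gene lists matched on mean counts, 95% of medians lay between -0.063 and 0.029 (permutation p = 1e-04, the smallest they can give). At 0.5 h the median was 0.067 (permutation p = 5e-04). It was 0.0912 in 0.5 h replicate 1, with 47 of 69 genes above 0, and 0.0234 in replicate 2, with 38 above 0. Both permutation p-values are across genes and do not measure the spread between libraries. The difference between the times was not tested for these genes.

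A hypothesis for this pattern is that RNA polymerase III may transcribe tRNA genes more at 24 h, with the reads counted toward the gene around them. The genes that hold the most did not rise clearly: AL592295.3, with 24, had 0.187 ± 0.198, and ZNF767P, with 7, had -0.239 ± 0.112. Of those that hold 4, LINC00324 had 0.545, AL021918.3 0.37, AL590385.2 0.274 and AL669831.3 -0.552. A trend with the number of tRNA genes held was not tested. More short RNA kept in the 24 h libraries, if kept alike, would raise short RNAs of both polymerases. The 9 tested short RNAs of RNA polymerase III had a median of 1.11 and the 8 of RNA polymerase II one of 0.0011 (exact permutation p = 0.0074 over 24310 splits of the genes). That p is across genes and does not measure the spread between libraries. Without 24 h replicate 1 the medians were 0.40 and -0.0795. The RNA polymerase III and small noncoding RNA list had a median of -0.00425 where a mean of at least 50 counts was required. The contrast of the 2 polymerases was not repeated at that filter and may rest on genes with few counts. These values argue only against short RNAs being kept alike, and uneven keeping among them was not tested. A regional change would also raise the 385 neighbours within 50 kb that hold no tRNA gene, and their median was -0.0041. The permutation p for the difference, again across genes, was 1e-05, the smallest that 100000 permutations can give. The pattern does not rest on the genes of the authors' deposited table, since the other 64 had a median of 0.20 (95% of random lists between -0.065 and 0.031), nor on 1 library, since the medians of the 24 h libraries were 0.337 and 0.226 and leaving out any 1 library left 0.22 to 0.33. It remains a hypothesis found and tested on the same data, and counts over the tRNA genes themselves were not analysed here.

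The fall of mtDNA counts has a biological explanation in the design, less mitochondrial transcription after MPP+, which was not tested apart from a technical one, that less mitochondrial material came along with the nuclei of treated cells. Thinning the libraries to 5983066 counts each left medians of -2.20 at 0.5 h and -2.13 at 24 h. Thinning keeps the expected share of each gene, and the fold changes were already scaled to library size. Its outcome was therefore largely fixed beforehand, and no conclusion on a cause is drawn from it. Less carry-over lowers all mtDNA genes alike, and at 0.5 h 0 of 15 mRNA and rRNA genes changed their share of the mtDNA counts (edgeR within mtDNA counts, smallest adjusted p = 0.991, median SE 0.17), so the carry-over explanation is consistent with the data at that time, as is a like fall of transcription. At 24 h 1 of 15 did, MT-RNR1 (change of share -0.72 ± 0.17, adjusted p = 0.005). This argues against like carry-over as the whole cause, and equally against a like fall of transcription, so it does not tell them apart. The call on MT-RNR1 was lost without control replicate 1 (-0.56) or 24 h replicate 1 (-0.58). For the other genes, 0 of 14 changed with MT-RNR1 left out (smallest adjusted p = 0.139), so that carry-over and transcription cannot be told apart for their shared fall, since both lower these genes alike.

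MT-RNR1, the gene nearest the heavy-strand promoter among these, took 6.22% and 5.06% of the tested mtDNA counts in untreated libraries, 5.89% and 5.89% at 0.5 h, and 3.16% and 3.76% at 24 h. Between 24 h and 0.5 h its share changed by -0.78 ± 0.18 (adjusted p = 0.00338), a call lost without 24 h replicate 1 (-0.65, adjusted p = 0.106), and that of MT-CYB by -0.49 ± 0.16 (adjusted p = 0.048). The call on MT-CYB was lost without control replicate 1 (adjusted p = 0.0602), control replicate 2 (0.0588), 0.5 h replicate 1 (0.136), 0.5 h replicate 2 (0.167), 24 h replicate 1 (0.174) or 24 h replicate 2 (0.137).

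The folds in the authors' deposited tables were smaller than those of edgeR. A DESeq2 fit on the 4 libraries compared with a zero-centred prior on the fold change came within 0.00475 of each log2 fold in the authors' deposited table at 0.5 h and within 0.00495 at 24 h. Without the prior the fit gave 2.25 for MT-CO1 at 0.5 h where the authors' deposited table has 1.43, and 2.95 for MT-RNR1 at 24 h where the authors' deposited table has 1.96. With the prior it called 18 genes at 0.5 h and 26 at 24 h, among them all 17 and all 24 of the authors' deposited tables. Genes with ribosomal DNA sequence took between 1.32% and 2.86% of the counts of a library.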
